A study of Mus musculus with 18 samples.

How the data were processed

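Values were read from the non-normalized table, which the authors provide with an intensity and a detection p-value for each probe and array. The intensity was taken as the unlogged bead summary per the file headers. The detection p-value was used as deposited, in steps of 1/936 as the values show. The series matrix holds normalized log2 values as deposited by the authors, with rank correlation 1 to the intensities, and these served only as an alternative. Groups were taken from the sample labels, and columns were matched to samples by name.

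Intensities were background corrected with normexp from the detection p-values, quantile normalized with an offset of 16 and log2 transformed by neqc in limma 3.58.1 under R 4.3.3. A probe was kept if its detection p-value was below 0.05 on at least 3 of 18 arrays, which kept 20239. Of the kept probes 17288 carried one gene symbol, and each of 10902 genes was represented by its brightest kept probe. The remaining 2951 kept probes without a symbol were counted only. Of the genes, 4238 had several kept probes, and disagreement with the probe used is stated where a gene is named. No genome build was named in the sources used here, so no coordinates are given.

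A linear model with 6 group means was fitted over all 18 arrays with moderated variances (12 residual degrees of freedom). There were 10 comparisons: TPA at 1 h and 3 h in each genotype, knockout against wild type at 0 h, 1 h and 3 h and as a mean, and the difference of the TPA responses at 1 h and 3 h. A gene was called at Benjamini-Hochberg adjusted p below 0.05 within its comparison. Gene groups were tested by camera with a preset correlation of 0.01 on 21 lists, adjusted over these lists within each comparison. The lists were immediate early transcription factors, ERK feedback regulators, ERK pathway output, plasminogen activators and proteases, growth factors, inflammatory and NF-kB genes, SRF and MRTF targets, p53 targets, proliferation, Hox genes, heat shock and unfolded protein response, epithelial and keratinocyte, neural and glial, cartilage and bone, fibroblast extracellular matrix, type I interferon, macrophage and blood, endothelial, skeletal muscle, liver, and neighbours of Dusp5. Lists can share genes, as with Spry4 among both ERK feedback regulators and ERK pathway output, so their tests are not separate evidence. The Serpinb family (4 tested genes) and sex chromosome markers (3 tested genes) had fewer than 5 tested genes and were counted only. Inducible genes were those raised at least 1.5-fold by TPA as the mean of both genotypes at 1 h or 3 h, at adjusted p below 0.05, and a joint F test over both response differences was adjusted within that set.

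Dusp5, Serpinb2, Fos, Egr1 and Dusp6 were always named, chosen before the data were examined. In addition the 10 largest changes in each direction among called genes with non-overlapping groups were eligible, or among all called genes for the mean and the response differences, and up to 4 called members of each list. Clone and predicted names were counted and not named. A base group with no detected array gives an at-least fold from the lowest level of detected probes.

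The alternatives tried were the series matrix values, quantile normalization without background correction, median scaling, a stricter detection threshold, no detection filter, the mean of all kept probes, a variance trend, array weights, only the compared arrays, a replicate block, an added 1.5-fold threshold, an estimated inter-gene correlation and the rotation test fry for lists, other inducible-gene thresholds, and each array left out in turn. Scaling to the median of the tested genes was chosen after seeing the data. A slide variant was not run because slide information was not used here.

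The linear model and the calling were tested on simulated normalized values with known shifts added to 50 genes of each size. The simulated noise was independent between genes and arrays. Background correction, normalization, filtering and the choice of probe were not part of this test. For knockout against wild type at 3 h it recovered 2% of shifts of 0.25, 56% of 0.5, 100% of 1 and 100% of 2 (log2), with 4.41% false calls. For the difference of the 3 h responses it recovered 0% of 0.25, 12% of 0.5, 98% of 1 and 100% of 2, with 6.19% false calls. The other comparisons were not tested this way.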

Results

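The series holds 18 Illumina mouse arrays of primary male embryonic fibroblasts. Cells labelled wild type and cells labelled as knockout of Dusp5, the gene of a nuclear ERK phosphatase, were each measured before and at 1 h and 3 h of treatment with 100 ng/ml of the phorbol ester TPA, with 3 arrays per group. No group received solvent alone, so changes ascribed to TPA also hold any effect of solvent, handling or time in culture. After filtering 20239 probes were kept, and 10902 genes were tested. Between 16675 and 18348 probes were detected per array. At 0 h the numbers were 17889 to 18348 in wild-type and 17308 to 17489 in knockout arrays. At 1 h the mean raw signal was 277 to 286 in wild-type and 236 to 259 in knockout arrays. The other ranges of these 2 measures overlapped between the genotypes. Arrays of the same group correlated at 0.991 to 0.996, and arrays of different groups at 0.972 to 0.995. The labels number the arrays of a group without saying whether they came from separate cultures, so every p-value measures only the spread between these samples, which may be partly technical. The comparisons, thresholds and gene lists were fixed before the data were examined.

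The targeted gene came down without going to background. Dusp5 signal in knockout cells was 54.1% of wild type before treatment (95% interval 47.4 to 61.8), 51.1% at 1 h (44.8 to 58.4) and 63.5% at 3 h (55.6 to 72.5). In log2 terms the differences were −0.89 ± 0.09 (standard error, limma adjusted p = 6.72e-06), −0.97 (adjusted p = 1.93e-06) and −0.65 (adjusted p = 1.45e-04), with 3 arrays in each group. Its probe was detected on all 9 knockout arrays. TPA raised Dusp5 signal by 1.95 (log2) in wild-type cells and by 1.87 in knockout cells at 1 h, and by 1.39 and 1.63 at 3 h. The difference between these responses was −0.08 at 1 h (95% interval −0.35 to 0.19, adjusted p = 0.956) and 0.23 at 3 h (−0.04 to 0.50, adjusted p = 0.575). Where the probe lies relative to the deleted part of the gene was not given in the sources used here, so the lower signal checks the genotype labels only in part.

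**Figure D1:**
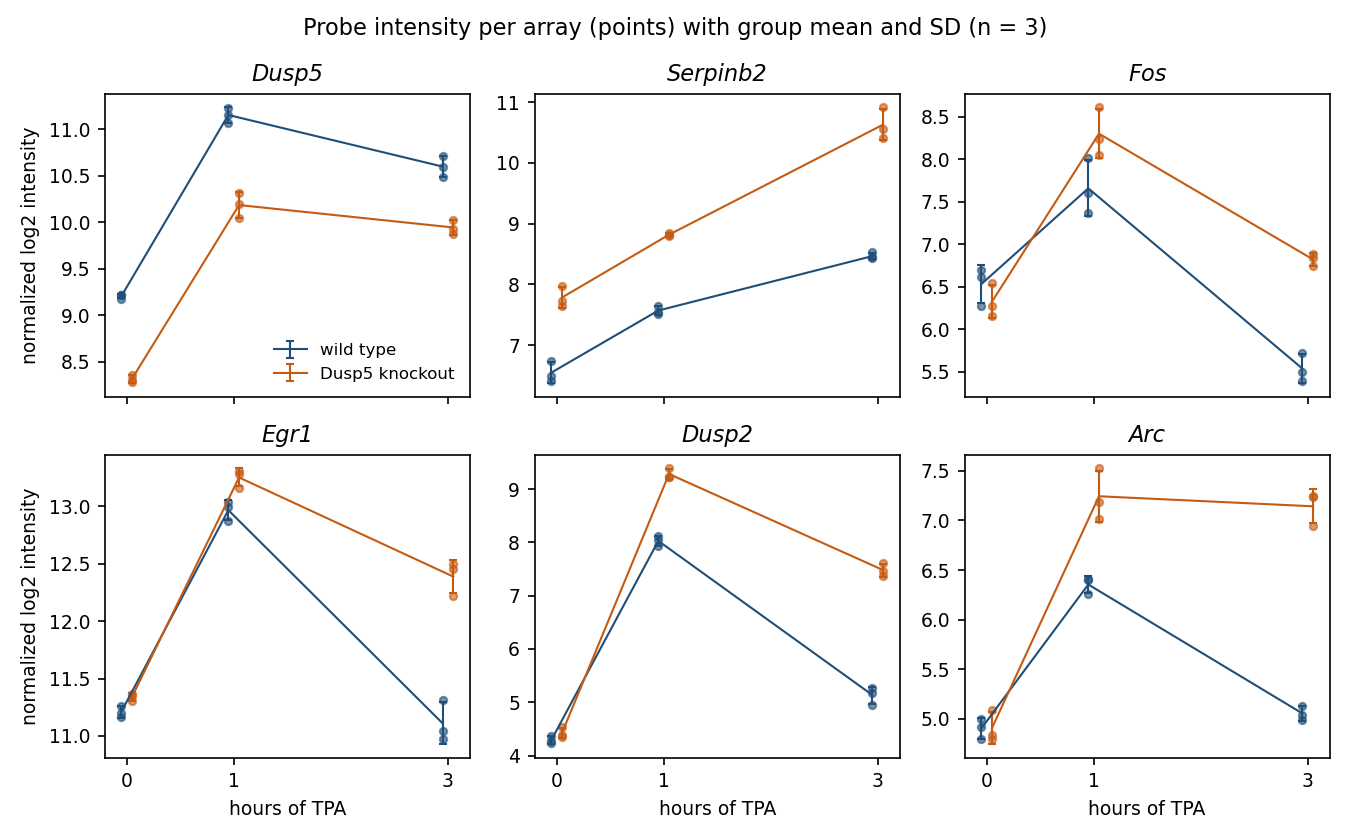
Normalized log2 intensity of 6 genes against hours of TPA in wild-type (blue) and knockout (orange) fibroblasts. Points are single arrays, lines join group means, and bars are standard deviations (n = 3 arrays).

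In wild-type cells 1 h of TPA raised the zinc-finger factor Egr3 by 4.60 ± 0.13 (log2, adjusted p = 6.89e-16), the cytokine gene Lif by 3.19 ± 0.13 (base detected on 2 of 3 arrays), and the AP-1 subunits Fosb and Junb by 2.73 and 2.64. Dusp2, the gene of another nuclear ERK phosphatase, was undetected before treatment and rose at least 10.7-fold. Egr4 rose by 3.17, from a base detected on 1 of 3 arrays, and the chemokines Ccl4 and Cxcl1 by 2.50 and 2.35. The largest fall was in Edn1, the endothelin-1 precursor (−2.90 ± 0.11, adjusted p = 1.12e-13), followed by the Ras-like gene Rasl11b (−1.71), the RhoA antagonist Rnd3 (−1.46) and the repressor Snai2 (−1.28). For all these genes the 3 treated arrays lay on one side of the 3 untreated ones, which chance alone gives for 10% of genes. In all, 369 genes were called, 205 higher and 164 lower, 184 of them by at least 1.5-fold. Another kept probe of Egr3 missed the threshold, and so did another of the growth factor Pdgfb (1.82 ± 0.13 on its main probe).

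Immediate early transcription factors led this response: of 29 tested, 16 rose and 2 fell, and 17 rose and 3 fell when adjusted over the list alone (camera adjusted p = 5.35e-30). Fos rose by 1.13 ± 0.16 (adjusted p = 1.04e-04) and Egr1 by 1.76 ± 0.10. Feedback regulators of ERK followed, with 6 of 15 up and 1 down (7 and 1 adjusted over the list alone, adjusted p = 4.25e-11), among them Errfi1 (2.13), which restrains the EGF receptor, Spry4 (1.85), Dusp4 (1.32) and Dusp6 (1.11). Of 22 ERK output genes, 9 rose (10 adjusted over the list alone, adjusted p = 2.34e-17), and of 19 growth factors 8 rose (10 adjusted over the list alone, adjusted p = 8.10e-13), including Il11 (1.73) and Vegfa (1.56). Inflammatory and NF-kB genes rose in 11 of 28 cases (14 adjusted over the list alone, adjusted p = 9.52e-16), with the inhibitor gene Nfkbia at 1.85 and Ccl2 at 1.25. Among 17 plasminogen activator and protease genes 4 rose (5 adjusted over the list alone, adjusted p = 9.96e-05), such as Mmp10 (1.55) and Serpinb2 (1.02 ± 0.12), the plasminogen activator inhibitor PAI-2. Of 18 p53 targets, 5 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 2.28e-05), with Plk3 at 1.12 and Gadd45a at 1.00. SRF and MRTF targets went the other way, although only Ccn1 (−1.14 ± 0.13) of 23 was called (1 adjusted over the list alone, adjusted p = 0.009). With median scaling over all probes, which shifted the median of all genes by −0.24, 1381 genes were called and 8.11% of them were higher. Scaling to the tested genes gave 642 calls with 76.6% higher, against 55.6% here.

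By 3 h in wild-type cells Pdgfb had risen by 3.13 ± 0.13 (log2), the lipase inhibitor Angptl4 by 2.86 ± 0.09, the stromelysin Mmp10 by 2.84, Lif by 2.83 and the glycoprotein hormone gene Stc1 by 2.75. Heme oxygenase Hmox1 rose by 2.51, and the chemokine Ccl3, undetected before treatment, at least 4.10-fold. Edn1 was down by −3.76 ± 0.11, the Cdc42 effector Cdc42ep3 by −3.33, the muscle ankyrin repeat gene Ankrd1 by −2.79 and the matricellular gene Ccn1 by −2.26. Egr1 was back near its starting value (−0.10, adjusted p = 0.573) and Fos was below it (−0.99 ± 0.16, adjusted p = 1.52e-04), while Serpinb2 had risen further (1.92 ± 0.12, adjusted p = 2.37e-10) and Dusp6 was up by 0.79. The total was 1744 genes, 851 higher and 893 lower, 599 of them by at least 1.5-fold. Other kept probes of Pdgfb and Angptl4 missed the threshold.

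The protease list rose in 9 of 17 genes with 1 fall at 3 h (10 and 2 adjusted over the list alone, camera adjusted p = 1.68e-05), led by Mmp10 and the collagenase Mmp13 (2.15, with 1 of 2 other probes called). ERK output genes rose in 14 of 22 cases and fell in 2 (15 and 2 adjusted over the list alone, adjusted p = 1.09e-09), as with Spry4 (1.49) and the potassium channel gene Kcnn4 (1.12). Of 15 feedback regulators, 10 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 5.39e-05): Errfi1 was up by 1.92 and Dusp4 by 1.69, and Dusp1 fell by 1.82. Growth factors rose in 11 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone, adjusted p = 3.99e-07), and inflammatory genes in 11 of 28 with 4 down (12 and 4 adjusted over the list alone, adjusted p = 4.06e-04), with Ccl2 at 2.02 and the deubiquitinase Tnfaip3 at −1.17. SRF and MRTF targets fell in 8 of 23 cases and none rose (9 adjusted over the list alone, adjusted p = 2.16e-08), including Srf itself (−1.11) and Ccn2 (−1.05). Of 10 epithelial and keratinocyte genes 3 rose (3 adjusted over the list alone, adjusted p = 0.0351), but the list was not called at adjusted p = 0.302 with an estimated correlation, 0.0935 in the series matrix values, 0.0917 without wild-type untreated array 2 and 0.0544 without wild-type 3 h array 3. The immediate early list had 7 of 29 up and 9 down and was not called as a list (7 and 10 adjusted over the list alone, adjusted p = 0.472). Median scaling shifted the median of all genes by −0.31 and gave 4821 calls with 5.39% higher, scaling to the tested genes shifted it by 0.11 and gave 2971 calls with 70.8% higher, and the split here was 48.8%.

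In knockout cells 1 h of TPA raised Dusp2 at least 24.7-fold from undetected. Egr4 rose by 4.82 ± 0.11 (log2, detected on 2 of 3 untreated arrays), Egr3 by 4.74, Fosb by 3.38 and Cxcl1 by 3.24. The cytokine gene Csf2 rose at least 5.08-fold from undetected. Fos rose by 1.98 ± 0.16 (adjusted p = 2.34e-08), Egr1 by 1.91 ± 0.10, Dusp6 by 1.10 and Serpinb2 by 1.04. Edn1 fell by 2.58, Rasl11b by 2.10, Rnd3 by 1.37 and the zinc-finger gene Zfp41 by 1.32. Of 590 genes called, 279 were higher and 311 lower, and 260 changed by at least 1.5-fold. The 205 genes raised in wild type and the 279 raised in knockout cells shared 173, with 5.25 expected by chance, and the lowered genes shared 115, with 4.68 expected. Another Egr3 probe missed the threshold. No array entered both sets, and the changes of all genes correlated at 0.678.

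In these cells immediate early factors rose in 17 of 29 cases with none down (20 up and 1 down adjusted over the list alone, camera adjusted p = 2.47e-38). Inflammatory genes rose in 16 of 28 (17 and 2 down adjusted over the list alone, adjusted p = 4.01e-23), ERK output genes in 10 of 22 (11 and 1 down adjusted over the list alone, adjusted p = 2.23e-18), feedback regulators in 7 of 15 (7 adjusted over the list alone, adjusted p = 2.63e-13) and growth factors in 9 of 19 (9 adjusted over the list alone, adjusted p = 9.34e-13). Examples were Nfkbia (2.04), the ubiquitin ligase adaptor Trib1 (2.05, base detected on 2 of 3 arrays), Errfi1 (2.42) and Pdgfb (2.16). Proteases rose in 5 of 17 (6 adjusted over the list alone, adjusted p = 2.88e-06), with the urokinase gene Plau at 0.75 (not called with median scaling), and p53 targets in 7 of 18 (7 and 1 down adjusted over the list alone, adjusted p = 5.97e-06), with Mdm2 at 0.95. Other kept probes of Pdgfb and 1 of 2 of Mdm2 missed the threshold. The SRF and MRTF list was not called here (0 rose and 2 fell, 3 adjusted over the list alone, adjusted p = 0.166), and its median turned upward relative to all genes under median-type scaling. Heat shock and unfolded protein response genes rose in 5 of 21 and fell in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.0104), a call lost at adjusted p = 0.129 with an estimated correlation. Of 7 neural and glial genes none was called (none adjusted over the list alone), and the list test at adjusted p = 0.0187 did not hold at adjusted p = 0.0625 with an estimated correlation, 0.0519 without knockout untreated array 2 and 0.103 without knockout 1 h array 3. Median scaling moved the median of all genes by −0.23 and left 1384 calls with 9.10% higher, and scaling to the tested genes gave 66.1% higher, against 47.3% here.

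At 3 h the knockout response was led by Pdgfb (3.42), Mmp10 (3.34), Egr3 (3.27), Lif (3.21) and Stc1 (3.14), in log2 units. Srxn1, a sulfiredoxin that repairs oxidized peroxiredoxins, rose by 3.03, and Dusp2 was still up at least 7.07-fold. Serpinb2 had risen by 2.85 ± 0.12 and Egr1 was still up by 1.05 ± 0.10 (adjusted p = 1.02e-07), as was Dusp6 by 0.69. The rise of Fos, 0.50 ± 0.16 (adjusted p = 0.0364), was not secure: its adjusted p lay between 0.0538 and 0.151 without any of the untreated knockout arrays 1 and 2 or the 3 h knockout arrays 1, 2 and 3, at values of 0.41 to 0.54, and it also missed the threshold in the series matrix values, without background correction, with median scaling and without the detection filter. Edn1 fell by 4.07, Cdc42ep3 by 3.10, Ankrd1 by 2.67, Rnd3 by 2.49 and the endothelial factor Klf2 by 2.13. The count was 2004 genes, 899 higher and 1105 lower, with 756 changed by at least 1.5-fold. Other probes of Pdgfb and Egr3 missed the threshold. Wild-type and knockout responses shared 532 raised genes (70.2 expected by chance) and 601 lowered genes (90.5 expected), and correlated at 0.785 over all genes.

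Proteases rose in 9 of 17 cases and fell in 1 in knockout cells at 3 h (10 and 2 adjusted over the list alone, camera adjusted p = 1.59e-07), with Mmp13 at 2.73 (1 of 2 other probes called) and Plau at 1.51. ERK output genes rose in 15 of 22 and fell in 1 (16 and 1 adjusted over the list alone, adjusted p = 2.53e-11), feedback regulators in 9 of 15 with 2 down (9 and 2 adjusted over the list alone, adjusted p = 7.46e-07), and growth factors in 11 of 19 with 4 down (15 and 4 adjusted over the list alone, adjusted p = 5.77e-09). Among them were Spry4 (1.73), Dusp4 (1.89) and Il11 (3.06). The immediate early list was still called, with 11 of 29 up and 6 down (12 and 6 adjusted over the list alone, adjusted p = 0.00295), and carried Arc (2.24), a neuronal activity gene, and Egr4 (2.21). Inflammatory genes rose in 11 of 28 and fell in 5 (13 and 5 adjusted over the list alone, adjusted p = 9.00e-05), with the cytokine Il1a at about 2.01, from a base detected on 1 of 3 arrays. SRF and MRTF targets fell in 9 of 23 (11 adjusted over the list alone, adjusted p = 2.49e-06), as Ccn1 did (−1.83), and p53 targets fell in 8 of 18 with 1 up (8 and 1 adjusted over the list alone, adjusted p = 0.0164), as did the death receptor Fas (−0.80). Epithelial genes rose in 3 of 10 (3 adjusted over the list alone, adjusted p = 0.00295), with Cldn4 at 1.23, and this list was lost at adjusted p = 0.0918 with an estimated correlation. Median scaling shifted the median of all genes by −0.12 and made 26.5% of the called genes higher, and scaling to the tested genes 55.9%, against 44.9% here.

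Before any TPA, knockout cells already held more Serpinb2 than wild-type cells (1.24 ± 0.12 log2, 2.36-fold, adjusted p = 4.40e-06). Uts2b, a urotensin peptide gene, was higher by 1.20 ± 0.11, the hyaluronan-degrading Cemip by 1.11, the retinaldehyde dehydrogenase Aldh1a3 by 1.02 and the gelatinase Mmp9 by 0.87. Lce1f and Ivl, which encode proteins of the cornified envelope of skin cells, were higher by 1.06 and 1.00. The water channel Aqp1 was lower by 1.32 ± 0.13, the Ras-like gene Diras2 by 1.01, the receptor Mrgprf by 1.00 and the ectonucleotidase Nt5e by 0.92. Fos (−0.21, adjusted p = 0.593), Egr1 (0.13, adjusted p = 0.585) and Dusp6 (0.27, adjusted p = 0.322) were not called. For Ivl, Nt5e and 1 of 2 further Aqp1 probes, other kept probes missed the threshold.

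In these untreated cells 202 genes were called, 105 higher and 97 lower, and 70 by at least 1.5-fold. Leaving out 1 array moved that count to 308 (wild-type array 1), 81 (wild-type array 2), 76 (wild-type array 3), 101 (knockout array 1), 80 (knockout array 2) or 128 (knockout array 3). Proliferation genes were lower as a list, with 1 of 21 called and 9 lower adjusted over the list alone (median −0.26, camera adjusted p = 4.00e-09). The called member was Ccne2, the cyclin E2 gene (−0.40, adjusted p = 0.0154), which lay between adjusted p = 0.0510 and 0.0653 (−0.40 to −0.39) without wild-type array 2 or knockout arrays 1 or 3. Protease genes were higher, with Serpinb2 and Mmp9 called of 17 (4 adjusted over the list alone, adjusted p = 0.0219), but the list missed the threshold at adjusted p = 0.0648 with an estimated correlation and at 0.0664 without wild-type array 1. The immediate early list had only Egr2 (0.69) called of 29 (2 adjusted over the list alone, adjusted p = 0.189). Median scaling shifted the median of all genes by −0.22 and gave 1548 calls with 2.0% higher, scaling to the tested genes gave 530 with 74.5% higher, and the split here was 52.0%.

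At 1 h of TPA the widest difference between the genotypes was in Egr4, higher in knockout cells by 1.75 ± 0.11 (log2, adjusted p = 1.59e-08). Higher too were Dusp2 by 1.26 ± 0.10 (adjusted p = 3.12e-07), the cytokine Csf2 by 1.10 and Arc by 0.89, next to Serpinb2 (1.25 ± 0.12), Lce1f (1.31) and Uts2b (1.22). Aqp1 was lower by 1.47, Nt5e by 1.31 and the matrix protein gene Smoc1 by 0.94. Fos was higher by 0.64 (adjusted p = 0.0401), but lay between adjusted p = 0.0754 and 0.224 (0.49 to 0.67) without wild-type arrays 1 or 2 or knockout arrays 1 or 2. Egr1 (0.28, adjusted p = 0.175) and Dusp6 (0.26, adjusted p = 0.404) were not called. Other kept probes of Nt5e and Smoc1, and 1 of 2 of Aqp1, missed the threshold. The 240 called genes, 119 higher and 121 lower, included 81 that differed by at least 1.5-fold. The count was 123 without wild-type array 1, 156 without wild-type array 3, 136 without knockout array 1 and 151 without knockout array 3.

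Immediate early factors were higher in knockout cells at 1 h, in 9 of 29 cases with none lower (12 adjusted over the list alone, camera adjusted p = 3.21e-15), including the mRNA decay factor Zfp36 (0.87), Arc and Egr4. Of 15 feedback regulators, 3 were higher (3 adjusted over the list alone, adjusted p = 2.81e-05): Dusp2, Dusp1 (0.69) and Dusp4 (0.70, with 2 of 3 other probes called), the last pair not called with median scaling. Inflammatory genes were higher in 6 of 28 cases (11, and 1 lower, adjusted over the list alone, adjusted p = 6.99e-09), with Il1a at 0.84, and proteases in 4 of 17 (4 adjusted over the list alone, adjusted p = 1.34e-05), with Mmp9 at 0.94. Growth factors gave 2 of 19 higher (6, and 1 lower, adjusted over the list alone, adjusted p = 0.00186), including Pdgfb (0.71; another probe not called, and not called with median scaling or as the mean of its probes), and ERK output genes 2 of 22 (5, and 1 lower, adjusted over the list alone, adjusted p = 0.00131), including Trib1 (0.86). Proliferation genes were lower in 5 of 21 cases (12 adjusted over the list alone, median −0.28, adjusted p = 1.92e-12), with Ccne2 at −0.51 ± 0.08. Hox genes were lower in 3 of 28 (5 adjusted over the list alone, median −0.10, adjusted p = 0.00636). The SRF and MRTF list (median 0.11, adjusted p = 0.00762) and the p53 list (adjusted p = 0.018) were higher with no member called, and 0 of 23 and 1 of 18 adjusted over the list alone. The p53 list missed the threshold without wild-type array 2 (adjusted p = 0.0858) or knockout array 2 (0.0789). Median scaling shifted the median of all genes by −0.22 and gave 889 calls with 2.36% higher, against 49.6% here and 65.7% with scaling to the tested genes.

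At 3 h the genotypes differed in 542 genes, the most of the 3 times here but the fewest with median scaling (179, against 1548 at 0 h and 889 at 1 h). Dusp2 was higher in knockout cells by 2.35 ± 0.10 (log2, adjusted p = 8.34e-12), Serpinb2 by 2.17 ± 0.12 (adjusted p = 2.40e-10) and Arc by 2.09 ± 0.12. Egr4 was higher by about 2.21 ± 0.11, against wild-type cells in which it was detected on 1 of 3 arrays. The secreted protease inhibitor Slpi was higher by 1.87 ± 0.13, Il1a by 1.59, the carbonic anhydrase Car2 by 1.54 ± 0.08 and Egr3 by 1.38, though another Egr3 probe was not called. Fos (1.29 ± 0.16, adjusted p = 4.30e-05) and Egr1 (1.28 ± 0.10, adjusted p = 6.83e-08) were both higher, and Dusp6 was not called (0.17, adjusted p = 0.559). On the lower side stood Aqp1 (−1.40, with 1 of 2 other probes called), the pseudokinase Trib2 (−1.08), Nt5e (−0.94) and Snai2 (−0.83). The called genes comprised 266 higher and 276 lower, 160 by at least 1.5-fold, and numbered 348 without wild-type array 3.

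Immediate early factors were higher in 12 of 29 cases and lower in 1 at 3 h (16 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 1.24e-14), among them Arc, Egr1, Egr4 and Fos. Proteases were higher in 7 of 17 (7 adjusted over the list alone, adjusted p = 1.08e-08), among them Mmp9 (1.05), Mmp10 (0.77) and the macrophage elastase Mmp12 (0.74). Feedback regulators were higher in 6 of 15 (8 adjusted over the list alone, adjusted p = 3.93e-07), with Dusp4 at 0.74, growth factors in 6 of 19 with 1 lower (8 and 1 adjusted over the list alone, adjusted p = 1.06e-06), with Il11 at 1.07 and the EGF receptor ligand Btc at 0.96, and ERK output genes in 7 of 22 with 2 lower (8 and 4 adjusted over the list alone, adjusted p = 0.0032), with Lif at 0.85. Proliferation genes were lower in 9 of 21 (12 adjusted over the list alone, median −0.30, adjusted p = 2.03e-11), including the survivin gene Birc5 (−0.57, with 1 of 2 other probes called) and Ccne2 (−0.50). Hox genes were lower in 7 of 28 (10 adjusted over the list alone, median −0.13, adjusted p = 4.98e-05), with Hoxa7 at −0.73 ± 0.10 and Hoxa5 at −0.62. SRF and MRTF targets were higher with 1 of 23 called (2 adjusted over the list alone, adjusted p = 0.00862), but not without knockout array 2 (adjusted p = 0.0598). Epithelial genes were higher in 2 of 10 (2 adjusted over the list alone, adjusted p = 0.0118), namely Pkp1 (1.08), a desmosome gene, and the tight junction gene Cldn4 (0.62, not called with median scaling), and the list was lost at adjusted p = 0.168 with an estimated correlation and at 0.203 without knockout array 1. Inflammatory genes, 3 of 28 higher and 2 lower (4 and 3 adjusted over the list alone), were not called as a list (adjusted p = 0.161). Scaling to the tested genes made 60.6% of the called genes higher, against 49.1% here.

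Averaged over the 3 times, Serpinb2 was the most raised gene in knockout cells (1.55 ± 0.07 log2, adjusted p = 9.65e-12), with Uts2b (1.24) and Aldh1a3 (1.17) also higher, as were Egr4 (1.35) and Dusp2 (1.25), which were at or near background before treatment. Fos (0.57 ± 0.09, adjusted p = 2.78e-04) and Egr1 (0.56 ± 0.06, adjusted p = 1.19e-06) were higher. Dusp6 was called by a small margin (0.23 ± 0.07, adjusted p = 0.0469). It was not called with median scaling or without the detection filter, nor (adjusted p 0.0583 to 0.105) without any of 13 of the 18 arrays, the exceptions being wild-type untreated array 3, knockout untreated array 2, wild-type 1 h array 3, knockout 1 h array 2 and wild-type 3 h array 1. Aqp1 was lowest (−1.40 ± 0.07), then Nt5e (−1.06), Smoc1 (−0.91, another probe not called) and Dusp5 (−0.84 ± 0.05). Of 1240 genes called, 573 were higher and 667 lower, but only 66 differed by at least 1.5-fold. Proliferation genes were lower in 16 of 21 cases (20 adjusted over the list alone, median −0.27, camera adjusted p = 1.09e-15), such as Ccne2 (−0.47), the kinase Aurkb (−0.41) and Cdk1 (−0.37). Hox genes were lower in 8 of 28 with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 1.79e-04). Immediate early factors were higher in 14 of 29 and lower in 2 (17 and 2 adjusted over the list alone, adjusted p = 4.06e-13). Median scaling shifted the median of all genes by −0.16 and gave 3675 calls with 3.84% higher, scaling to the tested genes 1946 with 71.2%, and the split here was 46.2%.

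The genotype differences recurred across the treatment times, whose means share no arrays. The calls at each time used variances estimated over all 18 arrays. The labels do not say whether the times of a genotype came from the same cell preparation. The times may therefore not be independent, and any difference between preparations could recur as well. Of the genes higher before treatment, 47 were also higher at 1 h (1.15 expected by chance) and 53 at 3 h (2.56 expected), and 75 were higher at both 1 h and 3 h (2.90 expected). For lower genes the shared numbers were 40 (1.08 expected), 47 (2.46 expected) and 69 (3.06 expected). Serpinb2, Uts2b, Cemip and Aldh1a3 on one side, and Aqp1, Nt5e and Smoc1 on the other, were called at every time. Over all genes the differences correlated at 0.432 between 0 h and 1 h, 0.336 between 0 h and 3 h, and 0.479 between 1 h and 3 h.

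**Figure D2:**
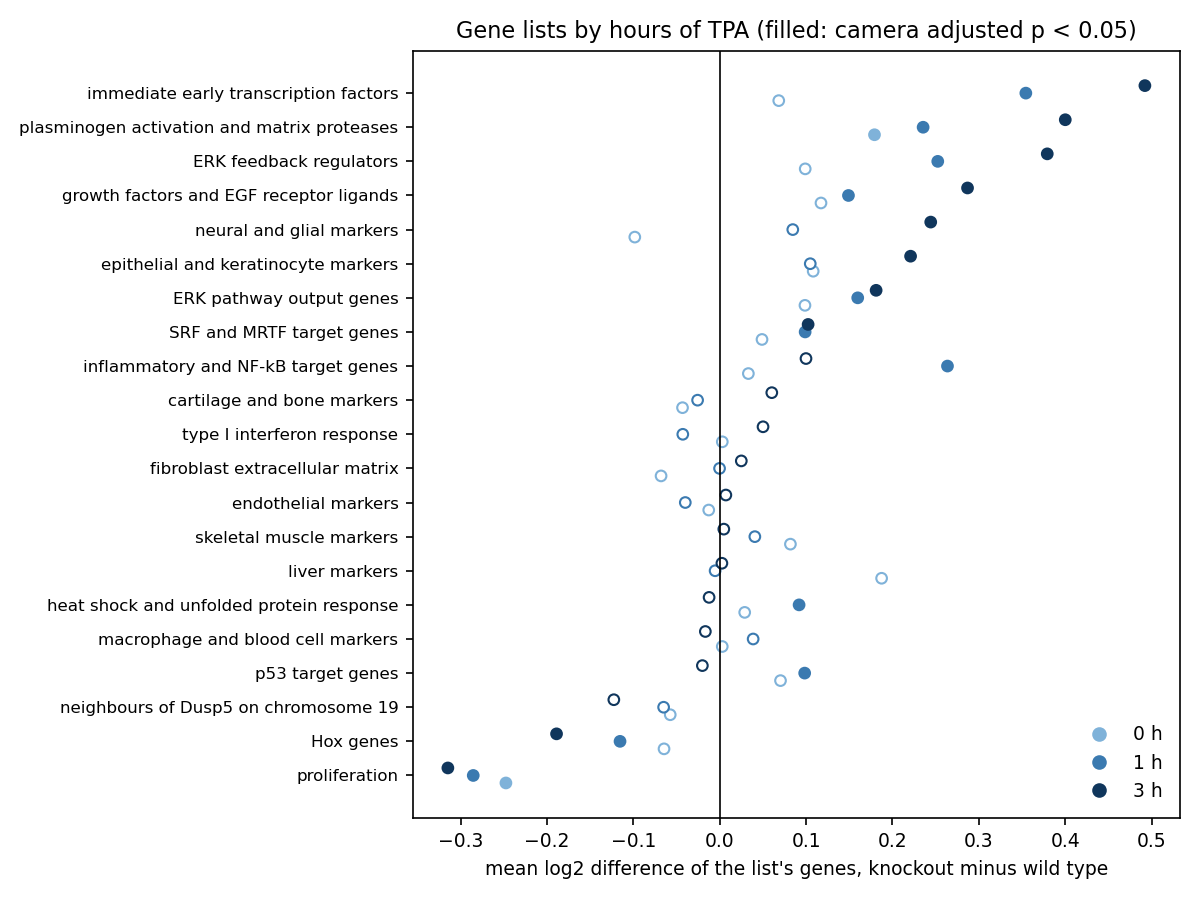
Mean log2 difference between knockout and wild-type fibroblasts for 21 gene lists before and at 1 h and 3 h of TPA. Filled points mark lists with camera adjusted p below 0.05.

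Tested directly, the 1 h response differed between the genotypes in 3 genes, all with larger rises in knockout cells. These were Egr4 (1.65 ± 0.16 log2, adjusted p = 2.07e-05), Dusp2 (1.12 ± 0.14, adjusted p = 8.96e-04) and Csf2 (1.09 ± 0.15, adjusted p = 0.00128). Their sizes were approximate, since before treatment Dusp2 and Csf2 were undetected in both genotypes and Egr4 was detected on 1 of 3 wild-type and 2 of 3 knockout arrays. Dusp2 and Csf2 were no longer called under either median-type scaling, and another Dusp2 probe missed the threshold. Fos (0.85 ± 0.23, adjusted p = 0.464), Egr1 (0.15, adjusted p = 0.922), Serpinb2 (0.01, adjusted p = 0.995) and Dusp6 (−0.01, adjusted p = 0.996) were not called. As lists, immediate early factors rose further in knockout cells, with Egr4 of 29 called (7 adjusted over the list alone, camera adjusted p = 1.15e-09), as did inflammatory genes, with Csf2 of 28 (5 adjusted over the list alone, adjusted p = 2.06e-06). Feedback regulators, with Dusp2 of 15 (2 adjusted over the list alone, adjusted p = 0.0147), missed the threshold at adjusted p = 0.172 with an estimated correlation, 0.101 by rotation test, 0.104 without wild-type untreated array 3 and 0.0759 without knockout untreated array 2. Unadjusted p lay under 0.05 for 640 genes.

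The 3 h response differed in 39 genes, and for 30 of them the change was more positive in knockout cells. Among them were Arc (2.08 ± 0.17 log2, adjusted p = 4.07e-07), Fos (1.49 ± 0.23, adjusted p = 0.0025) and Egr1 (1.15 ± 0.14, adjusted p = 1.49e-04). Dusp2 (2.21), Egr4 (2.11), Slpi (1.55), the somatostatin receptor Sstr2 (1.51), Car2 (1.39) and Il1a (1.38) were called too, but their sizes were approximate. Before treatment Dusp2, Sstr2 and Car2 were undetected in both genotypes, Slpi in wild-type cells and on 1 of 3 knockout arrays, and Il1a was detected on 1 of 3 arrays of each genotype. Egr4 was detected on 1 of 3 wild-type and 2 of 3 knockout arrays. Serpinb2 differed by 0.93 ± 0.17 (adjusted p = 0.0134), and without knockout untreated array 3 by 0.86 (adjusted p = 0.0565), and it was not called in a fit of only the compared arrays. Of the 9 genes with a more negative change, Ddit4l, an inhibitor of mTOR signalling (−0.85 ± 0.13, adjusted p = 0.00255), and Fam110b (−0.79) kept the call without any single array. Both lost it with median scaling, and Fam110b also as the mean of its probes, of which another was not called. Dusp6 was not called (−0.10, adjusted p = 0.887).

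Leaving out 1 array put that count at 24 (wild-type untreated array 3), 19 (knockout untreated array 3), 24 (wild-type 3 h array 1), 24 (wild-type 3 h array 2), 22 (wild-type 3 h array 3), 25 (knockout 3 h array 2) or 22 (knockout 3 h array 3). Immediate early factors had the more positive 3 h change in 7 of 29 cases (12 adjusted over the list alone, camera adjusted p = 3.70e-11), among them Arc, Egr1, Egr4 and Fos. Proteases did in 3 of 17 (4 adjusted over the list alone, adjusted p = 9.61e-04), feedback regulators in 1 of 15 (2 adjusted over the list alone, adjusted p = 4.59e-04), and growth factors in 1 of 19, Il11 at 0.88 (2 adjusted over the list alone, adjusted p = 0.0067). None of the 3 protease calls held without every array: Serpinb2 lost it without knockout untreated array 3 (adjusted p = 0.0565). Mmp12 lost it (0.0532 to 0.104) without any array but wild-type untreated array 3 and arrays 1 of both genotypes at 3 h, and Plau (0.0771 to 0.146) without any but wild-type untreated array 1 and knockout 3 h array 1. ERK output genes (1 of 22, 1 adjusted over the list alone, adjusted p = 0.20) and inflammatory genes (1 of 28, 2 and 1 more negative adjusted over the list alone, adjusted p = 0.421) were not called as lists. Median scaling shifted the median of all genes by 0.19 and made 100% of the called genes more positive, and the series matrix values and quantile scaling without background correction 64.4%, against 76.9% here.

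TPA raised 374 genes over both genotypes by at least 1.5-fold at adjusted p below 0.05, 138 of them at 1 h and 333 at 3 h. Of these, 84 (22.5%) responded differently in knockout cells by the joint test, among them Dusp2, Egr4, Arc, Fos, Egr1 and Serpinb2. By the sign of the difference alone, 76 of the 84 rose more at 3 h and 66 rose more at 1 h. Both differences use the same untreated arrays, so these signs are not independent. Over all genes the 1 h difference was called for only 3. The 3 h difference was positive for 75.1% of inducible genes with a median of 0.19 (log2), against −0.02 for all genes (camera adjusted p = 4.55e-22, adjusted over both times). That p compares genes within one grouping of the arrays: 8 of 100 splits of the arrays gave a median as far from 0, the highest other being 0.286. The median was 0.12 in the series matrix values and without background correction, and 0.41 with median scaling, where that of all genes was 0.19. At 1 h it was positive for 57.5% with a median of 0.03 (adjusted p = 1.09e-04), which was 0.0077 without knockout 1 h array 3 and 0.046 without knockout 1 h array 2. The inducible set and its share with a different response moved with the scaling, to 170 genes and 45.9% in the series matrix values, 171 and 45.6% without background correction, 220 and 31.8% with median scaling, and 484 genes, 53 of them called, with scaling to the tested genes. Tested over all genes instead of within the inducible set, 24 genes differed. Choosing the set by a 1.5-fold rise in wild type alone gave 338 genes, 57 of them called (16.9%). Slpi rose more in knockout cells, and 8 genes such as the ankyrin repeat gene Ankrd37 rose less at 3 h. Without wild-type 3 h array 2 the count was 52, and without wild-type untreated array 3 it was 55.

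**Figure D3:**
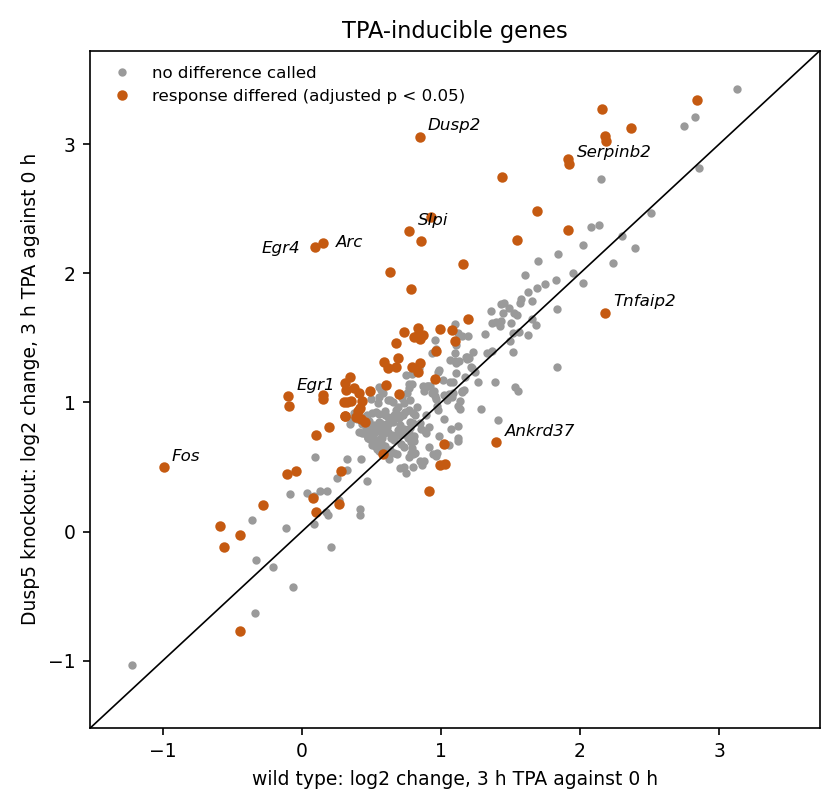
Change at 3 h of TPA in knockout cells against wild-type cells (log2) for 374 inducible genes. Orange points are the 84 genes with a different response, and the line marks equal change.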

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

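The tests of the Dusp5 signal, of array scaling and of epithelial cells, and the splits with the mean genotype difference removed, were chosen after the results were seen.

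A test of the difference between the genotypes' TPA responses picked out 3 genes at 1 h: Egr4 (1.65 log2), Dusp2 (1.12) and Csf2 (1.09). Before treatment Dusp2 and Csf2 were undetected in both genotypes, and Egr4 was detected on 1 of 3 wild-type and 2 of 3 knockout arrays, so these sizes were approximate. So were those of Dusp2, Egr4, Slpi, Sstr2, Car2 and Il1a at 3 h, which were each undetected on at least 1 array of both genotypes before treatment, and of Mmp12, undetected on 1 knockout array. At 3 h it picked out 39, named here where the naming rule allows. Positive values were those of Dusp2 (2.21), Egr4 (2.11), Arc (2.08), Slpi (1.55), Sstr2 (1.51), Fos (1.49), Car2 (1.39), Il1a (1.38), Fam83g (1.30), Egr1 (1.15), Serpinb2 (0.93), Mmp12 (0.92), Il11 (0.88) and Plau (0.70). Negative values were those of Ddit4l (−0.85), Fam110b (−0.79), Pex11g (−0.78), Apol9a (−0.77), Fbxo31 (−0.74), Lhfpl2 (−0.73), Dbp (−0.70), Rpap1 (−0.62) and Dlg3 (−0.60). Several calls ended when 1 array was left out. Each of the 12 arrays did so for Mmp12 except wild-type 0 h array 3 and arrays 1 of both genotypes at 3 h (adjusted p 0.0532 to 0.104), and for Plau except wild-type 0 h array 1 and knockout 3 h array 1 (0.0771 to 0.146). The exceptions were wild-type 0 h array 1, knockout 0 h array 2, wild-type 3 h array 2 and knockout 3 h array 1 for Pex11g (0.0726 to 0.111), and wild-type 0 h array 1 and arrays 2 of both genotypes at 3 h for Apol9a (0.0667 to 0.108). They were arrays 2 of both genotypes at 0 h for Fbxo31 (0.0667 to 0.129), wild-type 0 h array 2 for Dbp (0.0581 to 0.114), and knockout 0 h array 2 and knockout 3 h array 3 for Rpap1 (0.0654 to 0.126). For Dlg3 they were wild-type 0 h array 1 and knockout 0 h array 2 (0.0667 to 0.122), and for Lhfpl2 wild-type 0 h arrays 1 and 2, knockout 0 h array 2 and arrays 1 of both genotypes at 3 h (0.0627 to 0.0942). Serpinb2 lost its call without knockout 0 h array 3 (0.0565). Among inducible genes 84 had a different response.

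Probes without a gene symbol also held signal, which the comparisons of genes leave out. Of 2951 such probes, TPA changed 70 at 1 h and 251 at 3 h in wild-type cells, and 107 and 283 in knockout cells. Knockout and wild type differed in 20 at 0 h, 18 at 1 h, 46 at 3 h and 152 as a mean, and the 3 h response differed in 3.

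Other splits of the same arrays gave mixed answers. For TPA in wild type (369 genes at 1 h and 1744 at 3 h), TPA in knockout (590 and 2004) and knockout against wild type at 0 h (202), 1 h (240) and 3 h (542), 1 of 10 splits, the real one, gave as many calls and the highest other gave 0, but 10 splits are too few for a share under 0.05. The splits move single arrays, so they bear on chance only if the arrays of a genotype are separate cell preparations, which the labels do not say. With a single preparation per genotype they cannot tell genotype from a difference between preparations. For the mean over times 1 of 100 splits, the real one, gave as many calls (1240 against at most 14 elsewhere). If the arrays are separate preparations, this argues against chance. For the 1 h response difference chance was not argued against, with 9 of 100 splits reaching 3 and the highest other 25. For the 3 h response difference 10 of 100 splits reached 39 and the highest other gave 819, and for inducible genes 6 of 100 reached 84 and the highest other gave 157. The split with 819 calls swaps all genotype labels at 3 h and none at 0 h, so it turns the steady genotype difference into a response difference, a structure of the samples. With the mean genotype difference removed first, 7 of 100 splits reached the 3 genes at 1 h (highest other 4), 1 of 100 the 39 genes at 3 h (highest other 3) and 1 of 100 the 84 inducible genes (highest other 20). Chance was therefore argued against for the last 2 results only in this form and under the same condition. This form used the real labels to estimate the removed difference, so removing it could change only the counts of the other splits.

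The Dusp5 signal that remained in knockout cells was weighed first. Background hybridization was argued against, since the probe rose by 1.87 (log2) in knockout cells with TPA. A probe target outside the deleted part may explain the remainder, since the 1 h response differed from wild type by only −0.081. Wild-type transcript left in the cultures, from mixed or heterozygous cells, also stays possible, since the share of wild type varied by only 12.4 points over the 3 times. Cross-hybridization to another induced transcript was not tested.

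The larger 3 h response of inducible genes in knockout cells was weighed next. Array scaling was argued against only in part. The lowest median difference under the 3 other scalings was 0.12 (log2), but the series matrix values lay within 0.057 of plain quantile scaling. The main processing also used quantile scaling, so only median scaling was a separate check (0.41, against 0.19 for all genes). A single array was argued against, since the lowest share of genes with a larger response was 73.8% with each array left out. For inducible genes as a set, whether the response was amplified or returned to baseline more slowly cannot be told apart. Over them the mean change from 1 h to 3 h and the knockout excess correlated at 0.28. However, 7 of 100 splits, and 14 of 100 with the mean genotype difference removed, lay as far from 0 (highest others 0.438 and 0.424). Genes named beforehand differed, and they do not decide for the set. Egr1 stood at 11.21 (log2) before treatment and 11.11 at 3 h in wild-type cells, and at 11.34 and 12.39 in knockout cells. Multiplying the wild-type change cannot give that. A slower return does not describe Serpinb2, which still rose in wild-type cells from 7.57 at 1 h to 8.47 at 3 h. The median excess itself, 0.19, was matched by 8 of 100 splits (highest other 0.286) and by 2 of 100 with that difference removed (highest other 0.192).

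The cornified envelope genes Ivl and Lce1f, higher in knockout cells before TPA, were weighed last. A single array was argued against, since 12 of 12 calls held with each array left out. Whether epithelial cells in the knockout cultures explain the pattern could not be told from these values. Krt5, Epcam, Trp63, Perp and Cldn3 were detected on 0 of 18 arrays and Krt14 on 1, but no array shows that these probes respond. Of the list's markers detected on at least 17 arrays, Cldn4 (0.63), Krt19 (0.35) and Pkp1 (0.35) were higher in knockout cells. Krt18 (−0.35) and Cldn7 (−0.11) were lower. Lce1g (0.62), a family member of Lce1f outside the list, was higher too, but it belongs to the pattern to be explained. The epithelial list had a median of 0.070 (log2, bootstrap interval −0.11 to 0.35), but only 2 of its 10 members were clear of the detection floor.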

How the results depend on the processing

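Scaling to the median of the tested genes was chosen after the results were seen. Every count was a count of called genes, and the cause of a moved count was not tested except where stated.

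Adding a 1.5-fold minimum, which removes genes by construction, left 184 and 599 (TPA in wild type, 1 h and 3 h), 260 and 756 (TPA in knockout), 70, 81 and 160 (knockout against wild type at 0 h, 1 h and 3 h), 66 (mean over times) and 55 (inducible genes with a different response). Requiring inducible genes to rise 2-fold left 53.

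Median scaling gave 1381 and 4821 (wild type), 1384 (knockout, 1 h), 1548, 889 and 179 (genotype at 0 h, 1 h and 3 h), 1 (response difference at 1 h) and 3675 (mean). Scaling to the tested genes gave 642 and 2971 (wild type), 530 (genotype at 0 h), 1 and 25 (response differences), 1946 (mean) and 53 (inducible). The series matrix values gave 381 (genotype at 0 h), 5 and 59 (response differences), and quantile scaling without background correction 385, 5 and 59. A variance trend gave 358 (genotype at 0 h). Array weights gave 572 (wild type, 1 h), 473, 406 and 881 (genotype) and 82 (response difference at 3 h). Fitting only the compared arrays, with fewer degrees of freedom, gave 129, 90 and 281 (genotype) and 24 (response difference at 3 h).

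With 1 array left out the counts ranged over 267 to 356 and 1227 to 1789 (wild type), 414 to 503 and 1558 to 1766 (knockout), 76 to 308, 123 to 189 and 348 to 454 (genotype), 3 to 4 and 19 to 40 (response differences), 1051 to 1249 (mean) and 52 to 86 (inducible). The mean Dusp5 difference ranged from −0.86 to −0.81.

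The replicate numbers were not taken as pairs, since only 10 of 45 pairs with the same number correlated above 0.1, but 15 of 18 arrays correlated best with their own number, which hints at shared structure. With the replicate block the counts were 425 and 1892 (wild type), 634 and 2093 (knockout), 260, 278 and 599 (genotype), 3 and 46 (response differences), 1328 (mean) and 85 (inducible). Of 484 calls of named genes the replicate block ended 2, Aurkb at 1 h (adjusted p = 0.0526) and Spry4 at 3 h (0.0511) between the genotypes. As a random block within genotype the correlation was 0.0415. A slide block was not run, since no slide was named in the sources used here.

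No call of a named gene turned round. List tests, which were repeated only with the estimated correlation, the rotation test, the replicate block, the series matrix values and each array left out, did not turn round either. Of 484 calls of named genes, median scaling lost 87, scaling to the tested genes 23, the mean of kept probes 18, no filter 17, the series matrix values 14, quantile scaling 14, the variance trend 6 and array weights 3. Fitting only the compared arrays, not possible for the 75 calls of the mean over times, kept 360 and lost 49. The stricter detection threshold could be compared for 481 calls and lost 0. Of the 484, 403 held without each array in turn. Of 77 called list tests, the estimated correlation lost 9 and the rotation test 2. Detected probes reached down to between 4.59 and 4.72 (log2) per array.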

Other observations

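The values in this part come from comparisons and lists fixed before the data were examined, and no test here was chosen after the results were seen.

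In knockout cells 3 h of TPA raised 4 of 7 neural and glial genes (4 adjusted over the list alone, camera adjusted p = 0.00412), including the axonal growth protein gene Gap43 (1.09 log2), the intermediate filament genes Nes (0.48) and Nefm (at least 1.20-fold, undetected before treatment), and in wild-type cells 1 (1 adjusted over the list alone, adjusted p = 0.702). The difference of the 3 h responses was called for the list (0 genes, 1 adjusted over the list alone, adjusted p = 4.59e-04), and at 3 h knockout cells held more Nes (0.59, another probe not called; 1 of 7 called, 2 adjusted over the list alone, adjusted p = 0.00533). Of 12 cartilage and bone genes, 2 rose in knockout cells at 3 h (4 adjusted over the list alone, adjusted p = 0.00397), among them the chondrocyte factors Sox9 (2.37) and Sox5 (1.28, with 1 of 2 other probes called), and 2 in wild-type cells (2 adjusted over the list alone, adjusted p = 0.154). For this list the difference of responses was not called (adjusted p = 0.213). Hox genes fell in 9 of 28 cases in knockout cells at 3 h with 1 up (9 and 1 adjusted over the list alone, adjusted p = 0.0056), such as Hoxc6 (−0.67) and Hoxd10 (−0.66).

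Heat shock and unfolded protein response genes were higher in knockout cells at 1 h by the list test, with Hmox1 (0.58) of 21 called (3 adjusted over the list alone, adjusted p = 0.037), but their median was −0.00 against a mean of 0.09. The call was lost at adjusted p = 0.211 with an estimated correlation, 0.0624 by rotation test, 0.118 and 0.136 without wild-type arrays 1 and 2, and 0.116 and 0.0565 without knockout arrays 2 and 3. Averaged over times, epithelial genes were higher with 3 of 10 up and 1 down (3 and 1 adjusted over the list alone, adjusted p = 0.0216), but not at adjusted p = 0.216 with an estimated correlation or without knockout arrays 1 at 1 h (0.0615) or 1 at 3 h (0.0608). No comparison called the lists of fibroblast extracellular matrix (mean over times 4 of 25 higher and 5 lower, 5 and 5 adjusted over the list alone, adjusted p = 0.914), type I interferon response (0 of 11 higher, 1 lower, 1 adjusted over the list alone, adjusted p = 0.914), macrophage and blood cells (0 of 12, 0 adjusted over the list alone, adjusted p = 0.679), endothelium (0 of 8, 0 adjusted over the list alone, adjusted p = 0.880), skeletal muscle (2 of 11 higher, 1 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.356) or liver (0 of 5, 0 adjusted over the list alone, adjusted p = 0.455).

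Of 13 tested neighbours of Dusp5 on chromosome 19, 3 were lower in knockout cells over the times (3 adjusted over the list alone, camera adjusted p = 0.139): the adducin gene Add3 (−0.38 ± 0.06, adjusted p = 3.72e-04), the cohesin gene Smc3 (−0.30, adjusted p = 0.0209), for which another probe pointed the other way, and the acyl-CoA synthetase gene Acsl5 (−0.18, adjusted p = 0.022), whose 2 other probes were not called. Of 4 tested Serpinb genes only Serpinb2 was higher in knockout cells, and Serpinb6b fell at least 1.38-fold with TPA at 3 h in wild type, to undetected. Of 3 tested sex chromosome genes none differed between the genotypes.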
